A study of Mus musculus with 6 samples.

How the data were processed

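Myeloid-derived suppressor cells (MDSCs) were grown from mouse femur marrow for 7 days with GM-CSF and IL-6, each at 40 ng/mL, per the labels' protocols. The cells were CD11b+ Gr1+ per the labels, and 3 wild-type libraries (C57BL/6) and 3 Pim1 knockout libraries were made by a Smart-seq2 protocol, which copies polyadenylated RNA into full-length cDNA. The labels' design text calls the 3 libraries of a genotype biological replicates.

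The values used here came from the authors' deposited table of 1 comparison, with 24312 rows and 1 pooled value per gene and genotype. The deposited expression values were read as FPKM because the column layout is that of a Cuffdiff gene comparison, although the header names neither the unit nor the software. Per the file headers, the table also holds a log2 fold change, a test statistic (used as a score per gene), a p-value and a q-value. Aligner, annotation, program versions and the scaling between libraries are not given in the sources used here. The deposited q-values equalled a Benjamini-Hochberg adjustment of the deposited p-values over the 11079 rows marked as tested, within 5.28e-07. A further 13227 rows were marked as not tested, and 6 rows (Fth1, Ftl1, Lyz2, Psap, Rn45s and Spp1) were marked as too deeply covered to estimate, so a 0 in them is a failed estimate. Of all rows, 7650 were at 0 in both genotypes. A spreadsheet had turned 27 symbols into dates, 3 of them in called rows, and no mitochondrial chromosome row was present.

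Values per library were not used here, because the table pools them. The planned limma fit on log2(value + 1), principal components, correlations between libraries, and leaving out or regrouping of libraries were therefore not run. Gene calls are therefore the authors' own: a deposited q-value under 0.05. Depth per library is unknown, because the deposited values are not counts, and no interval for counting error is given. The error printed beside a log2 fold change is that fold change divided by the deposited test statistic. Its median over tested genes was 0.287. It was 0.481 in the fifth of genes with the lowest means (median mean value 1.02) and 0.238 in the fifth with the highest (median mean value 86.3). The deposited p-values correspond to normal deviates 1.74 times the deposited test statistic (5th to 95th percentile 1.69 to 1.78 over 9500 genes), so the printed error is wider than the one behind the p-values. Reading the test statistic itself as a normal deviate was added as an alternative after the data were seen. The smallest deposited p-value, 5e-05, is shared by 667 genes and gives the smallest q-value, 0.000831.

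Gene lists and the rule for named genes were fixed before the data were examined. Of 36 lists, 28 had at least 5 tested members. They were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the signed normal deviates of the deposited p-values, two-sided. The test used a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 28 lists. This took the place of the planned camera test, which needs library values, and for the same reason no correlation between genes could be estimated and fry could not be run. The median log2 fold change of each list was also placed among those of 10000 random lists matched on mean value in 20 bins. Test statistics were simulated for this comparison over 11048 genes. Recovered were 82% of genes changed by a log2 of 1 and 98% of genes changed by a log2 of 2, with 3.74% false calls. The simulation drew and tested with the narrower errors behind the deposited p-values and assumed them to be right. It does not cover the wider errors printed here. On simulated deviates the shifted list was called and 0 of the unshifted lists were. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.

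The rule named Pim1, Pim2 and Pim3. It then took the 6 genes with the largest fold change each way among called genes with a mean value of at least 10 and an ordinary symbol. It also took up to 3 called members with the smallest adjusted p of each function list (the most abundant member where none was called), and the 2 most abundant members of each cell-type or quality list. It gave 90 genes. Its condition that the replicates of the genotypes not overlap could not be tested, and ties at the smallest q-value were broken by the test statistic, a choice made after the data were seen. Genes named outside the rule are said to be so in the text of the Results. The figure captions and the sections after the Results also name genes outside the rule.

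Coordinates are those of the authors' deposited table, with starts counted from 1. The submitters' processing notes name mm10, but only 12.8% of the loci of 23180 matched symbols overlapped their gene in the GENCODE M21 annotation of that build, although 99.5% lay on the same chromosome, so the build of these coordinates is left open. Called shares near Pim1 were compared by Fisher's exact test, two-sided, within 5 Mb on each side, and within 1, 2 and 10 Mb as alternatives. Other alternatives were an adjusted p under 0.1 or 0.01, a mean value of at least 10, no filter, pseudocounts of 0.1, 1 and 5, median centring and quantile normalization. Further ones were removal of genes within 10 Mb of Pim1 or of rows that share a locus, and for lists also assumed correlations of 0.05 and 0.1, ranks, and the deposited test statistic. Genes that share reads with near-identical copies (class I H2 genes, the Bcl2a1 and Ear families, ribosomal protein genes with pseudogenes) and rows that share a locus (2431 tested rows, 220 of them called) are uncertain, since how the authors assigned such reads is not given in the sources used here.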

Results

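The series measured RNA of bone-marrow-derived MDSCs, a mixed population of immature granulocytic and monocytic cells that restrain T cells, from wild-type and Pim1 knockout mice. Pim1 encodes a serine/threonine kinase that is induced by cytokines acting through STAT3 and STAT5. Each genotype had 3 libraries, and the comparison asks what differs between the genotypes in these cells. Loss of Pim1 cannot be told apart in it from a difference in sex between the libraries or from the segment around Pim1. The authors' deposited table gives 1 pooled value per gene and genotype, so no spread between libraries stands beside a value. Without the 6 rows too deeply covered to be estimated, the values summed to 780671 in wild type and 745811 in Pim1 knockout, and the 10 largest held 13.1% and 11.7% of them. Across tested genes the median log2 fold change was 0.01.

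The targeted gene was lower in the knockout. Pim1 (chromosome 17, 29627990 to 29632404 in the coordinates of the table) fell from 90.2 in wild type to 22.7 in Pim1 knockout in the authors' deposited table, a log2 fold change of -1.99 with an error of 0.25 and the smallest adjusted p the table gives, 0.000831. Transcript from the locus was thus still measured in the knockout, and the table does not show which part of the gene it came from. Of the related kinases, Pim2 rose from 2.21 to 3.64 (adjusted p = 0.0168), whereas Pim3 was at 13.7 and 13.2 (adjusted p = 0.882) in the authors' deposited table. Pim1 stayed called and Pim2 was not called (adjusted p = 0.622) with the test statistic read as a normal deviate.

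The pooled values of Pim1 knockout held more RNA of interferon-induced and granulocyte genes and less of several class I H2, lipid handling, hypoxia and immediate early genes. Such values cannot separate a change within cells from a different share of cell types in this mixed population. Of 11079 tested genes, 1498 (13.5%) passed an adjusted p of 0.05 in the authors' deposited table. Of these, 752 were higher and 746 lower in Pim1 knockout. Their median absolute log2 fold change was 0.72, and 475 changed at least 2-fold, 270 higher and 205 lower. The 2-fold count was 244 at a pseudocount of 1 and 123 at a pseudocount of 5. With the test statistic read as a normal deviate that count was 298. Among called genes with a mean of at least 10 and a symbol other than a Gm, Rik or locus name, the largest rises in the authors' deposited table were those of Plac8 (2.08 to 55.3, 26.6-fold), Npl, a sialic acid lyase (12.3 to 135.3, 11.04-fold), and Rtp4 (7.72 to 80.7, 10.5-fold). Next in the authors' deposited table came the chemokine Ccl12 (22.2 to 219.1, 9.85-fold), Irf7 (5.07 to 42.5, 8.39-fold) and the protease cathepsin E, Ctse (12.8 to 103.0, 8.06-fold). Their errors lay between 0.27 and 0.49 on the log2 scale. Under the same limits, the largest falls in the authors' deposited table were those of H2-Q4 (18.8 to 2.00, 9.39-fold), the heparan sulfate proteoglycan Sdc1 (149.9 to 23.5, 6.38-fold) and Retnla (98.6 to 16.8, 5.87-fold). The authors' deposited table then had the ribonuclease Rnase2a (120.4 to 21.4, 5.62-fold), Ly86 (136.2 to 26.0, 5.23-fold) and the Wnt pathway transcription factor Tcf7l2 (17.1 to 3.49, 4.89-fold), with errors from 0.24 to 0.36. Outside the rule, C920025E04Rik fell 6.50-fold, from 30.5 to 4.70 in the authors' deposited table. H2-Q4 and Rnase2a have near-identical relatives, so their values are uncertain. The count of calls rests on how the deposited test statistic is turned into a p-value: read as a normal deviate it called 366 genes, 361 of them among the 1498.

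**Figure D1:**
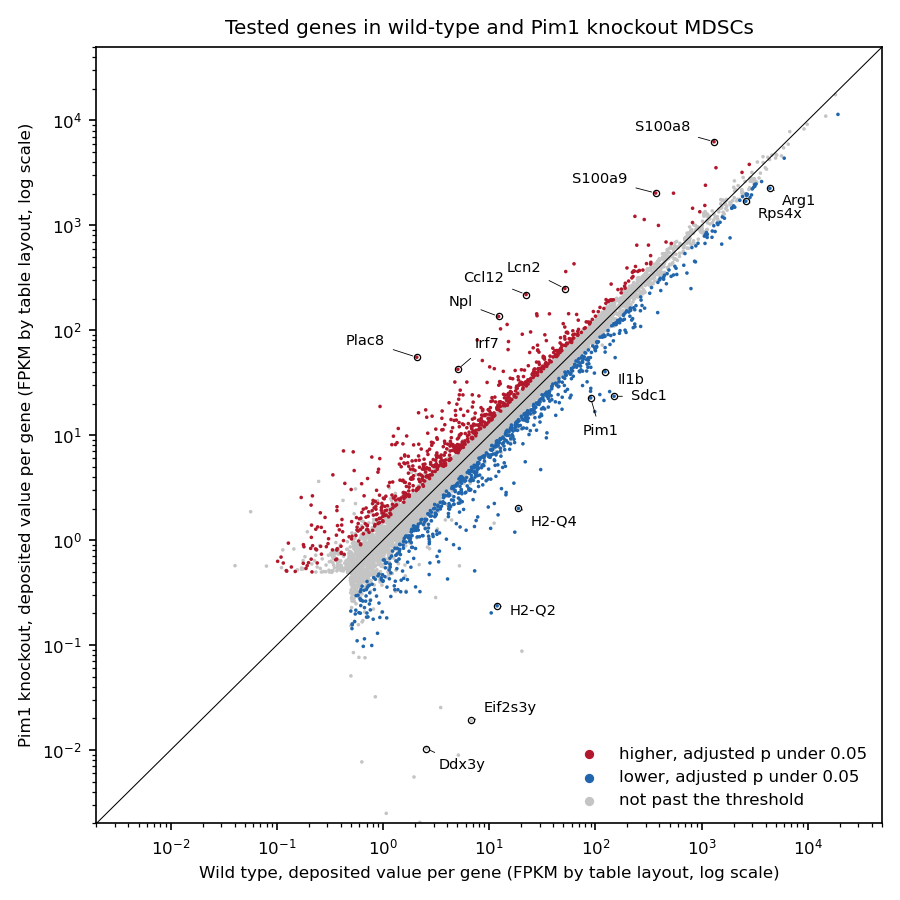
Each point is 1 tested gene of the authors' deposited table, with its wild-type value on the x axis and its Pim1 knockout value on the y axis, both in the FPKM the table layout implies and on log scales. The line marks equal values, the 752 genes called higher are red, the 746 called lower are blue, grey genes did not pass an adjusted p of 0.05, and genes listed at 0 in either genotype are not drawn.

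Interferon response genes rose together. Of 22 tested members, 21 rose and 1 fell in Pim1 knockout, and the same counts held adjusted over the list alone. The list's median log2 fold change was 2.40, above those of all 10000 random lists matched on mean value. The list test, cameraPR, gave an adjusted p of 7.4e-18, and of 5.3e-07 at an assumed correlation of 0.1. It sets the genes of a list against other genes, so its p-values do not measure the spread between libraries. Beside Rtp4 and Irf7, the transcription factor that amplifies type I interferon production, Oasl2 rose from 8.62 to 51.5 (5.97-fold, error 0.26) in the authors' deposited table. Read as a normal deviate, the test statistic called 19 members higher and 0 lower. Gbp2 was the member that fell, from 28.7 to 20.2 (adjusted p = 0.00561) in the authors' deposited table, and was named after its value was seen. Class I antigen presentation genes also passed the list test (5 higher and 1 lower of 13, 6 higher and 1 lower adjusted over the list alone, median log2 fold change 0.21, adjusted p = 0.0041). The peptide transporter subunit Tap1 rose from 21.5 to 41.7, the class I transactivator Nlrc5 from 1.31 to 2.41 and the immunoproteasome subunit Psmb9 from 138.5 to 194.1 in the authors' deposited table. That class I call was lost when genes within 10 Mb of Pim1, where Tap1 and Psmb9 lie, were left out. It was also lost at an assumed correlation of 0.1 and with log2 fold changes at a pseudocount of 0.1 or 1, with or without median centring or quantile normalization. Read as a normal deviate, the test statistic called 1 gene of the list. In this comparison the markers of mature neutrophils had a median of 1.02.

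**Figure D2:**
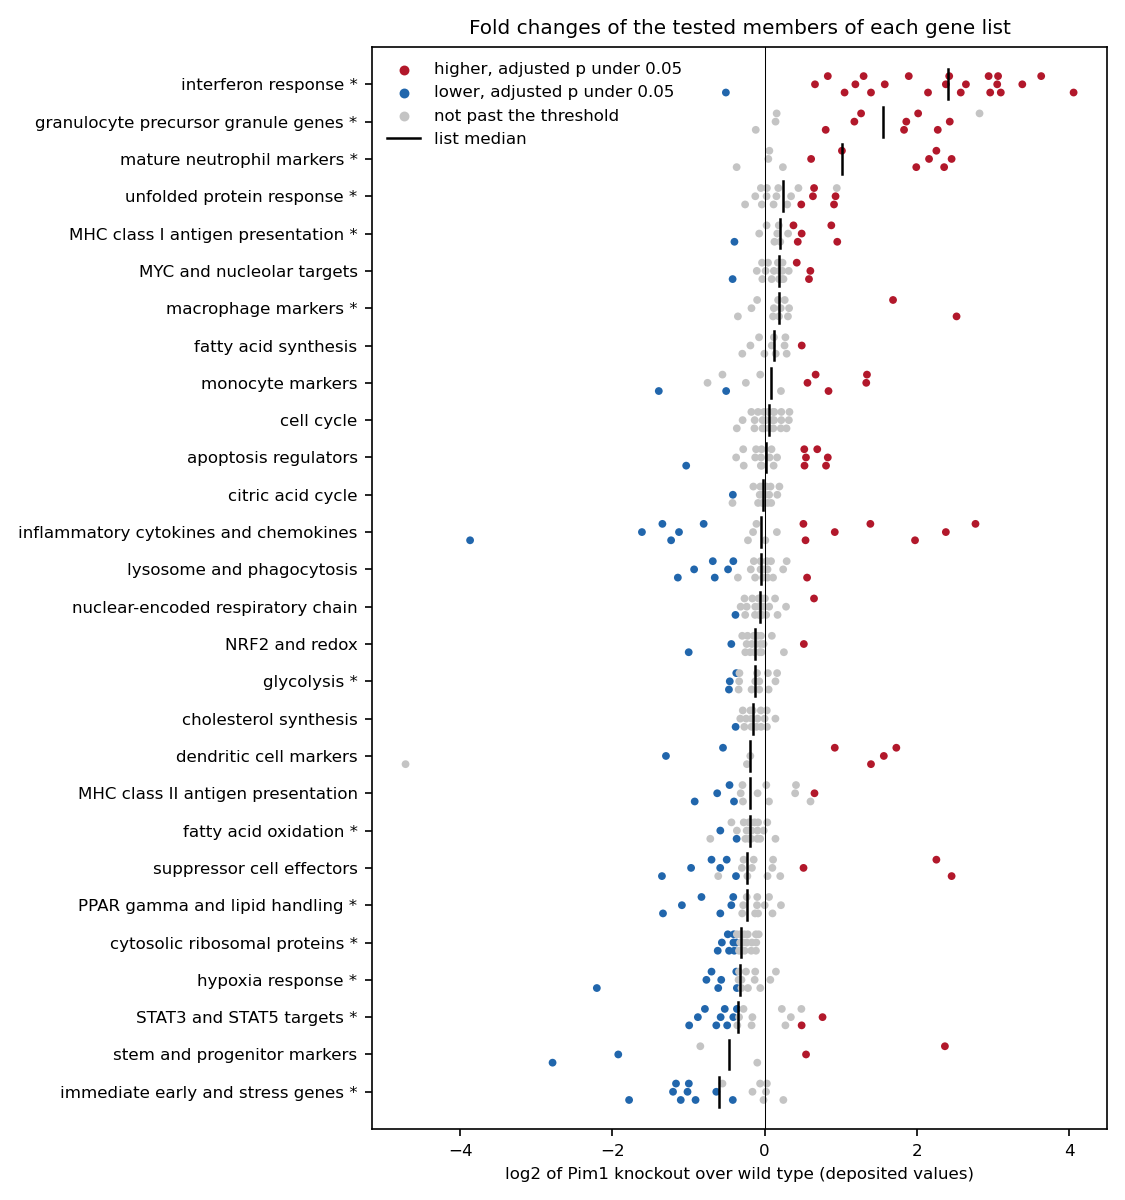
Each point is a tested member of a gene list with at least 5 tested members, placed by its log2 fold change of Pim1 knockout over wild type in the authors' deposited table, with black bars at list medians and an asterisk on the 13 of 28 lists that passed the list test. The interferon response list lies farthest to the right, with a median of 2.40, and immediate early and stress genes farthest to the left, with a median of -0.59.

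Granulocyte genes were higher in Pim1 knockout. Of 12 tested granule genes of granulocyte precursors 8 rose and 0 fell (9 rose adjusted over the list alone), with a median log2 fold change of 1.55 and an adjusted p of 1.5e-06 for the list. Of 11 tested markers of mature neutrophils 7 rose and 0 fell, with the same counts adjusted over the list alone, a median of 1.02 and an adjusted p of 8.9e-06. This median of 1.02 is given beside other lists for comparison, and no link between them was tested. S100a8 and S100a9, which form the calcium-binding protein calprotectin, rose from 1308 to 6257 (4.78-fold, error 0.24) and from 369.3 to 2029 (5.49-fold, error 0.23) in the authors' deposited table. The siderophore-binding Lcn2 rose from 51.6 to 249.8 (4.84-fold, error 0.25) in the authors' deposited table. Of the list, its most abundant gene, Chil3, and Prtn3 were at 732.9 and 676.3 (adjusted p = 0.703) and at 42.9 and 47.9 (adjusted p = 0.582) in the authors' deposited table. Only 4 granule genes had a mean of at least 10, of which 2 rose, too few for the list test under that filter, and others that rose were low, such as Mpo (0.232 to 0.826) and Elane (1.54 to 3.72) in the authors' deposited table. Among mature neutrophil markers, 8 had a mean of at least 10, of which 6 were called. The receptor gene Cxcr2 of that list was at 3.29 and 3.41 (adjusted p = 0.925) in the authors' deposited table. Another receptor gene of the list, Csf3r, rose from 5.26 to 8.03 in the authors' deposited table but was not called with the test statistic read as a normal deviate. Prtn3, Mpo, Elane, Cxcr2 and Csf3r were named outside the rule. With the test statistic read as a normal deviate, 5 and 6 genes of these lists were called higher.

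Markers of monocytes did not pass the list test (5 higher and 2 lower of 12, 5 and 4 adjusted over the list alone, median log2 fold change 0.08, adjusted p = 0.37). Ly6c2 rose from 392.4 to 997.1, whereas the receptor gene Csf1r was at 319.9 and 269.7 (adjusted p = 0.265) in the authors' deposited table. The monocyte list passed as higher when only genes with a mean of at least 10 were kept and with log2 fold changes at a pseudocount of 5. Macrophage markers passed the list test (adjusted p = 0.043, median 0.19), although only 2 of 13 rose and 0 fell, also adjusted over the list alone. Those 2 were also called with the test statistic read as a normal deviate. The complement gene C1qb was at 1515 and 1756 (adjusted p = 0.372) in the authors' deposited table. The other abundant marker, Spp1, listed at 9022 in Pim1 knockout, had a failed estimate in wild type in the authors' deposited table. The macrophage call was lost at assumed correlations of 0.05 and 0.1, with a mean of at least 10 and with log2 fold changes at a pseudocount of 0.1. Dendritic cell markers went both ways (4 higher and 2 lower of 9, also adjusted over the list alone, adjusted p = 0.43), with a median of -0.19 and a mean of -0.15 although the test pointed up. Bst2, which interferon also induces and which is a member of both lists, rose from 245.3 to 646.6, and the integrin Itgax, CD11c, fell from 59.0 to 24.03 in the authors' deposited table.

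Genes of suppressor function went in both directions. Of 19 tested members 3 rose and 6 fell, also adjusted over the list alone, and the list did not pass its test (median log2 fold change -0.23, adjusted p = 0.10). Its median was at percentile 0.32 of random lists matched on mean value. S100a8 and S100a9, which are also on the mature neutrophil list, were among those that rose. Slc7a2, a cationic amino acid transporter that carries arginine, fell from 75.7 to 29.7 (2.55-fold, error 0.23) in the authors' deposited table. Arginase 1, the enzyme by which MDSCs deplete arginine, was named after its value was seen: Arg1 fell from 4394 to 2250 (1.95-fold, error 0.28) in the authors' deposited table. Cytokine and chemokine genes also divided, 7 higher and 6 lower of 18, with the same counts adjusted over the list alone (median -0.05, mean 0.01, test pointing up, adjusted p = 0.98). The suppressor list had 2 genes called each way and this list 4 each way with the test statistic read as a normal deviate. Both lists stood beside the mature neutrophil marker median of 1.02. The monocyte chemoattractants Ccl7 (62.9 to 429.5, 6.83-fold) and Ccl2 (288.4 to 1135, 3.94-fold) and the interferon-induced Cxcl10 (6.16 to 32.1, 5.21-fold) rose in the authors' deposited table. Named after their values were seen, the neutrophil chemoattractant Cxcl1 (17.4 to 1.19), Il1b (123.2 to 40.3), Il1a (57.6 to 22.7), Cxcl3 (235.6 to 108.1) and Il6 (5.30 to 2.26) fell in the authors' deposited table.

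Of the 4 lipid lists, PPAR gamma and lipid handling and fatty acid oxidation passed the list test as lower in Pim1 knockout. The first had 0 higher and 6 lower of 17, also adjusted over the list alone (median log2 fold change -0.23, adjusted p = 0.000813). Pparg itself, the nuclear receptor that controls lipid storage, fell from 15.6 to 7.34, the lipoprotein lipase inhibitor Angptl4 from 7.32 to 2.90 and the monoglyceride lipase Mgll from 71.4 to 40.2 in the authors' deposited table. Angptl4 lies within 10 Mb of Pim1, and without genes of that region the list still passed (cameraPR, 15 tested, adjusted p = 0.0028). Fatty acid oxidation passed with 2 lower and 0 higher of 22 (1 lower adjusted over the list alone), 20 of the 22 having a fold change below 0 (median -0.19, adjusted p = 0.0028). Its called members were Acsl1, which activates long-chain fatty acids (22.1 to 14.8), and the oxidation enzyme Hadhb (65.7 to 51.0), which fell in the authors' deposited table. An assumed correlation of 0.1 and log2 fold changes at a pseudocount of 0.1 ended both list calls, and fatty acid oxidation also lost its call at a pseudocount of 1 and after median centring. With the test statistic read as a normal deviate, 3 genes of the first list and 0 of the second were called, all lower. The mature neutrophil markers, with a median of 1.02, differed in the same comparison.

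Hypoxia response genes passed the list test as lower (0 higher and 7 lower of 18, 10 lower adjusted over the list alone, median log2 fold change -0.32, adjusted p = 3.3e-05). Of its members the vasodilator peptide gene Adm fell from 3.23 to 0.700, Ero1l from 60.9 to 41.1 and the histone demethylase Kdm3a from 5.70 to 3.74 in the authors' deposited table. Glycolysis passed the list test with 3 lower and 0 higher of 15 (6 lower adjusted over the list alone, median -0.12, adjusted p = 0.033). Pgk1 fell from 925.4 to 674.1, the glucose transporter Slc2a1 from 142.6 to 110.2 and Pfkfb3 from 3.72 to 2.69 in the authors' deposited table. Of hypoxia genes 1, Adm, and of glycolysis genes 0 were called with the test statistic read as a normal deviate. The glycolysis median was at percentile 7.11 of random lists, inside their central 95%, whereas those of the other 12 lists that passed lay outside it. The medians of 4 lists that did not pass also lay outside it. Hypoxia and glycolysis lists were lower in the comparison in which the mature neutrophil markers had a median of 1.02. The glycolysis call was lost under 9 settings and held with ranks of the deviates, without genes within 10 Mb of Pim1 and without interferon response genes.

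Cytosolic ribosomal protein genes were slightly lower throughout. All 24 had a fold change below 0, 8 fell and 0 rose (13 fell adjusted over the list alone), with a median log2 fold change of -0.31 and an adjusted p of 1.1e-07 for the list. Rps4x fell from 2594 to 1693, Rpl5 from 574.8 to 389.6 and Rpl23 from 1494 to 1069 in the authors' deposited table. Values of ribosomal protein genes with pseudogenes are uncertain. The list's adjusted p by cameraPR was 0.046 with log2 fold changes at a pseudocount of 0.1 and 0.039 after quantile normalization. At an assumed correlation of 0.1 the adjusted p was 0.0030. With the test statistic read as a normal deviate, 0 ribosomal protein genes and 0 unfolded protein response genes were called. Beside the falls of ribosomal protein genes stood a median of 1.02 for mature neutrophil markers. Unfolded protein response genes passed in the other direction, 5 higher and 0 lower of 18 (6 higher adjusted over the list alone, median 0.24, adjusted p = 0.0019). Asparagine synthetase, Asns (5.24 to 10.0), the chaperone cofactor Sdf2l1 (126.1 to 195.8) and the pseudokinase Trib3 (2.81 to 5.29) rose in the authors' deposited table. The unfolded protein response call was lost at an assumed correlation of 0.1, with a mean of at least 10 and with log2 fold changes at a pseudocount of 0.1.

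STAT3 and STAT5 target and pathway genes passed their test as lower, with 2 higher and 9 lower of 20 (4 and 11 adjusted over the list alone, median log2 fold change -0.35, adjusted p = 0.0038). The cytokine Osm fell from 52.1 to 26.2, Socs2, an inhibitor of cytokine signalling, from 59.5 to 34.5 and the shared receptor chain of IL-6 family cytokines, Il6st, from 5.46 to 2.97 in the authors' deposited table. An assumed correlation of 0.1 and log2 fold changes at a pseudocount of 0.1 ended that call. Immediate early and stress genes, listed as a sign of how cells were handled, fell as a group (0 higher and 9 lower of 16, 10 lower adjusted over the list alone, median -0.59, adjusted p = 3.7e-06). Its most abundant members were the chaperone Hspa8, which fell from 1404 to 1051, and Ier3, at 409.9 and 367.2 (adjusted p = 0.518) in the authors' deposited table. The normal deviate reading called 2 genes of the STAT list and 6 of the immediate early and stress list, all lower. Beside these falls stood the same mature neutrophil marker median, 1.02.

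The other 10 function lists did not pass their tests. Some passed under alternatives: cholesterol synthesis, MYC and NRF2 lists with ranks, cholesterol synthesis and class II lists with a mean of at least 10, and the lysosome list with the deposited test statistic or at a pseudocount of 5. Class II presentation (1 higher and 4 lower of 14, median -0.19, adjusted p = 0.24) held H2-Aa and H2-DMb2, which fell from 859.0 to 454.6 and from 19.0 to 12.3 in the authors' deposited table. It also held H2-Eb1, which rose from 95.7 to 150.8 in the authors' deposited table. H2-Aa, H2-DMb2 and H2-Eb1 lie within 10 Mb of Pim1, where genotype cannot be told apart from the segment around it. Without genes of that region, 6 members of the list were tested. MYC and nucleolar targets (3 higher and 1 lower of 20, median 0.19, adjusted p = 0.058) held Srm (40.4 to 61.4) and Rrp9 (10.4 to 15.6), which rose, and Npm1 (447.2 to 334.3), which fell in the authors' deposited table. Among NRF2 and redox genes (1 higher and 2 lower of 20, median -0.12, adjusted p = 0.056) the superoxide dismutase Sod1 rose from 220.4 to 315.1 in the authors' deposited table. Its relative Sod2 fell from 170.4 to 125.9 and the cystine transporter Slc7a11 from 5.52 to 2.77 in the authors' deposited table. Of apoptosis regulators (6 higher and 1 lower of 20, median 0.01, adjusted p = 0.31), Bcl2l1 rose from 32.3 to 56.5 and Bid from 18.1 to 29.3 in the authors' deposited table. Bcl2a1a, whose value is uncertain because near-identical copies exist, fell from 194.5 to 95.2 in the authors' deposited table. Lysosome and phagocytosis genes (1 higher and 6 lower of 22, median -0.05, adjusted p = 0.054) included the proton pump subunit Atp6v0d2 (190.3 to 100.2), Marco (11.4 to 5.16) and Axl (82.6 to 52.5), which fell in the authors' deposited table. Of these 5 lists only H2-Aa, Slc7a11, Bcl2l1, Bcl2a1a, Atp6v0d2 and Marco stayed called with the test statistic read as a normal deviate.

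Fatty acid synthesis (1 higher and 0 lower of 11, median 0.12, adjusted p = 0.34) had Scd2, which rose from 53.7 to 75.4 in the authors' deposited table. Cholesterol synthesis (0 higher and 1 lower of 17, 0 adjusted over the list alone, median -0.16, adjusted p = 0.072) had Mvd, which fell from 69.5 to 53.4 in the authors' deposited table. In the citric acid cycle (0 higher and 1 lower of 18, median -0.02, adjusted p = 0.54) Idh3g fell from 120.3 to 90.1 in the authors' deposited table. In the respiratory chain (1 higher and 1 lower of 24, median -0.06, adjusted p = 0.40) Ndufa4 rose from 233.0 to 365.5 and Uqcrfs1 fell from 190.8 to 146.4 in the authors' deposited table. None of these 5 genes was called with the test statistic read as a normal deviate. By the authors' test 0 of the 24 cell cycle genes were called, and 5 had an unadjusted p under 0.05 (median 0.06, list adjusted p = 0.51). Pcna was at 213.0 and 174.4 (adjusted p = 0.147) in the authors' deposited table. Adjusted over the list alone, counts differed from those over all tested genes among these 10 lists only in cholesterol synthesis, apoptosis regulators (2 lower) and lysosome and phagocytosis (7 lower).

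Stem and progenitor markers (2 higher and 2 lower of 6, 3 lower adjusted over the list alone, median -0.47, adjusted p = 0.46) held Ly6a, which interferon also induces and which rose from 235.5 to 1217 (5.17-fold, error 0.26) in the authors' deposited table. At a pseudocount of 5 that list passed as higher, opposite to its median. Another member, Kit, rose from 3.24 to 4.73 in the authors' deposited table. Gata2 fell from 0.700 to 0.185 and Siglecf, found on eosinophils, from 7.68 to 4.64 in the authors' deposited table. Kit, Gata2 and Siglecf were not called with the test statistic read as a normal deviate. The eosinophil granule gene Prg2 was at 0.552 and 0.931 (adjusted p = 0.398) in the authors' deposited table. No T and NK cell marker was tested, and Nkg7 and Lck were at 0.425 or less in both genotypes in the authors' deposited table. Beside Sdc1, the B cell gene Cd79b was at 0.968 and 1.28 (adjusted p = 0.564) in the authors' deposited table. The platelet genes Pf4 and Ppbp were at 4360 and 4234 (adjusted p = 0.916) and at 116.2 and 101.4 (adjusted p = 0.447) in the authors' deposited table. The endothelial gene Pecam1 rose from 3.69 to 7.77, and Kdr was at 2.17 and 2.55 (adjusted p = 0.478) in the authors' deposited table.

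Sex-linked genes differed between the genotypes. Xist, transcribed from the inactive X chromosome of female cells, rose from 5.21 to 7.21 (error 0.27 on the log2 scale) in the authors' deposited table. The Y-linked Eif2s3y was at 6.79 in wild type and 0.0191 in Pim1 knockout without a call (adjusted p = 0.537) in the authors' deposited table. With the test statistic read as a normal deviate, Eif2s3y was called lower and Xist was not called.

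**Figure D3:**
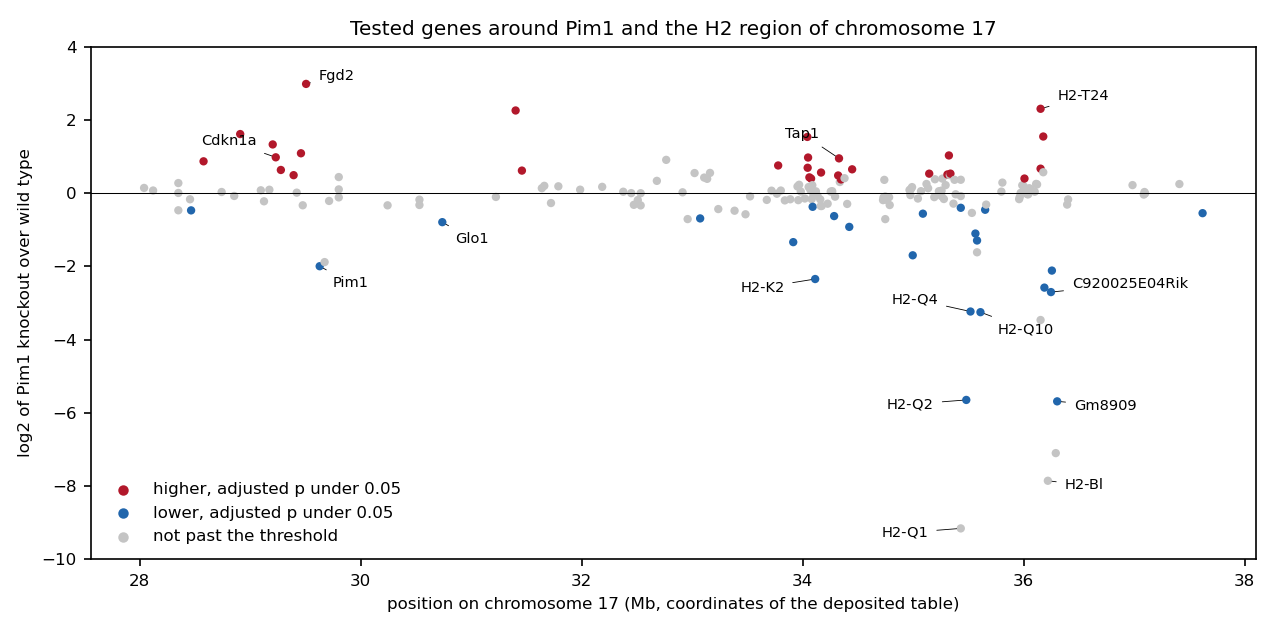
Each point is a tested gene on chromosome 17 near Pim1 and the H2 region, placed by its position in the coordinates of the authors' deposited table (Mb) and its log2 fold change of Pim1 knockout over wild type. Genes called higher are red, genes called lower are blue and the rest grey, genes listed at 0 in either genotype are left out, and H2-Q2 and Gm8909 lie at -5.65 and -5.69 while H2-T24 lies at 2.31.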

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

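Fth1, Psap and Spp1 had values in Pim1 knockout outside any comparison, because their wild-type estimates had failed and were listed at 0. They stood at 24867 (Fth1, the ferritin heavy chain), 6372 (Psap) and 9022 (Spp1, osteopontin) in the authors' deposited table. No explanation beyond the failed estimate was tested, and no direction follows from these values.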

How the results depend on the processing

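Of 86 named genes other than Pim1 with a numeric fold change, 74 were called, and these and Pim1 kept their direction after quantile normalization, while pseudocounts cannot turn a direction and median centring moved all genes by only 0.01. Pim1 also kept its call under each setting that tested it. Chosen after seeing the data were the normal deviate reading, an adjusted p under 0.01, the removal of genes or rows and a pseudocount of 1. So were, for lists, the assumed correlations, ranks and the deposited statistic.

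Read as a normal deviate, the test statistic called 204 genes higher, 162 lower and 298 changed at least 2-fold, and 36 of the 74 called named genes lost their call. With a mean of at least 10 the counts were 350 higher, 365 lower and 123 over 2-fold, where fewer genes were tested, and an adjusted p under 0.01 left 458 lower. Genes over 2-fold numbered 244, 242 and 245 at a pseudocount of 1, alone, after median centring and after quantile normalization, and 123 at a pseudocount of 5, which shrinks the fold changes of low genes by construction. Without a filter 678 were higher and 660 lower over 16662 genes, and 6 called named genes lost their call. The share of higher calls ran from 49.0% to 55.7%. An assumed correlation of 0.1 and log2 fold changes at a pseudocount of 0.1 each left 6 lists called. The cause of the changes whose construction does not show it was not tested. The odds of a call near Pim1 exceeded those elsewhere in windows of 1, 2, 5 and 10 Mb.

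No paired analysis was possible because the table pools the libraries of each genotype, so the replicate block could not be fitted. For the same reason the leaving out of each replicate, other splits of the 6 libraries, other count normalizations and tests, array weights, limma without trend, fry and an estimated correlation were not run. Depth is unknown. Genes of low value had the larger errors.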

Other observations

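The genes in this paragraph were named after their values were seen and were not tested as groups. Stefin genes of chromosome 16, inhibitors of cathepsins, rose: Stfa1 from 5.34 to 26.9, Stfa2 from 15.1 to 65.4, Stfa3 from 28.0 to 143.4 and Stfa2l1 from 15.2 to 78.0 in the authors' deposited table. Beside Ccl2, Ccl7 and Ccl12, the chemokine gene Ccl8 rose from 0.938 to 18.8 in the authors' deposited table. The eosinophil-associated ribonuclease row Ear2,Ear3 fell from 110.1 to 24.4 and the row Ear6,Ear7 from 34.5 to 9.44, and Ear1 was listed at 0 in Pim1 knockout against 1.15 in wild type in the authors' deposited table. Tartrate-resistant acid phosphatase, Acp5 (153.4 to 54.9), the fusion receptor gene Dcstamp (30.1 to 13.3) and the macrophage elastase Mmp12 (1547 to 661.6) fell in the authors' deposited table. So did carbonic anhydrase Car4 (793.9 to 249.4), fibronectin, Fn1 (386.0 to 147.3) and transglutaminase Tgm2 (266.9 to 108.7) in the authors' deposited table. Stefin and Ear genes are families of near-identical copies, so the values of single members are uncertain.

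Genes near Pim1 were called more often than others. Within 5 Mb of Pim1, 41 of 186 tested genes (22.0%) were called, against 1456 of 10892 elsewhere (13.4%, odds ratio 1.83, Fisher's exact test, p = 0.0015, two-sided, adjusted p = 0.0021 over 4 windows), with Pim1 itself left out. Beside it, Fgd2 rose from 0.437 to 3.47, the cell cycle inhibitor Cdkn1a from 198.3 to 392.2, and Glo1 fell from 70.5 to 40.8 in the authors' deposited table. Fgd2, Cdkn1a and Glo1 were named outside the rule.

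The tests on class I H2 genes, on whether the libraries differ in sex and on the chromosomes of interferon genes were chosen after the results were seen. Class I H2 genes on chromosome 17, from H2-K2 (start 34111604) to Gm8909 (end 36305482), stood apart: of 22 tested rows 11 fell, 10 of them at least 2-fold, and 3 rose. H2-Q2 fell from 11.9 to 0.237, H2-K2 from 14.4 to 2.84 and H2-Q10 from 4.05 to 0.426 in the authors' deposited table, while H2-T24 rose from 0.896 to 4.45 and H2-K1 was at 730.9 and 696.0 without a call. H2-Bl, at 20.3 and 0.0875, was not called either (adjusted p = 0.0648) in the authors' deposited table.

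None of the 3 explanations tested could be excluded. For reads that moved between class I copies, summed gains came to 23.2% of summed losses outside H2-K1 and H2-D1. The summed change of those 2 abundant genes was -347.8 with an error of 253.3, so they could hide the rest at that error. It is the wider error, not the one behind the p-values. H2-D1 was called lower (1304 to 990.8, adjusted p = 0.0352) in the authors' deposited table, but not with the test statistic read as a normal deviate. For a segment of another strain carried along with the targeted allele, the 2.5 Mb window near Pim1 with the highest share of genes at least 2-fold lower (8 of 43) ranked 5 of 820, at the bound set for it and below 4 windows of chromosome 6, but without the class I rows the best rank was 43 of 819. For an effect of Pim1 loss, a fall of 9 loading and subunit genes was looked for, but their median log2 fold change was 0.38. This excludes nothing, since these genes can be regulated apart from the H2 genes and some of them, such as Tap1 and Psmb9, lie near Pim1. Genotype cannot be told apart from the segment around it.

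Y-linked genes were close to 0 in Pim1 knockout, and all 4 on the list were at least 4-fold lower. Kdm5d and Uty were not tested, and Ddx3y and Eif2s3y were not called by the deposited q-value, although both were called with the test statistic read as a normal deviate (adjusted p = 3.3e-05 and 0.0061). Ddx3y was at 2.56 and 0.0103, and Kdm5d and Uty were listed at 0 in Pim1 knockout against 0.454 and 0.462 in wild type in the authors' deposited table. Wild-type Xist stood at 72.2% of the Pim1 knockout value, which is consistent with wild-type libraries from mice of both sexes and knockout libraries from females, a hypothesis that pooled values cannot test library by library. Whether sex lies behind other changes cannot be told apart from genotype. X-linked genes were called in 49 of 332 cases (14.8%) and autosomal genes in 1449 of 10742 (13.5%), an odds ratio of 1.11 (Fisher's exact test, p = 0.51, two-sided), and autosomal genes may differ by sex too.

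The rise of interferon response genes may come from loss of Pim1, from 1 library or culture, or from the segment around Pim1. A difference in sex between the libraries may also lie behind that rise and cannot be told apart from genotype. The called genes that rose lie on 13 chromosomes and 0% of them on chromosome 17. All 22 tested members remained when genes within 10 Mb of Pim1 were left out, so this outcome was fixed by the choice of the list. At these positions the segment could not act on them in cis whatever their values, and an effect in trans was not tested. A rise carried by 1 library cannot be told apart from a rise in all 3. The errors of these genes were 1.12 times those of genes of like mean (95% bootstrap interval of the median 1.02 to 1.18). This was under the bound of 1.5 set beforehand, but that bound presumed errors estimated gene by gene. Among 981 genes with a mean of at least 100 the errors ran from 0.98 to 1.15 times their median (5th to 95th percentile). Errors estimated gene by gene from 3 libraries per genotype would run from 0.42 to 1.54 times the true error. Larger ratios, such as 3.76 for Ddx3y and 6.76 for Eif2s3y, also arose where a value was close to 0 (median 5.05 over 10 genes with a value under 0.05), so they do not show that the errors carry the spread between libraries.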
